A study of Homo sapiens with 2 samples.

How the data were processed

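The data were 1 poly-A RNA-seq library from human gallbladder and 1 from hCdH-chols, with 1 file per library. Per the labels' protocols, 1 μg of total RNA per sample was poly-A selected and made into a stranded (dUTP) library. Per the submitters' processing notes, the tools named were bcl2fastq 2.20, cutadapt 1.5, STAR 2.5.2b and RSEM 1.2.31, with the genome build hg19. The notes as used here give no roles, order or parameters for them. Each deposited file lists 22318 genes by symbol, with RefSeq transcript accessions, a mean transcript length, an effective length, an expected count and TPM. Genes in both files were the same and in the same order. RSEM's expected counts in the deposited files are estimates that share out reads among transcripts, and 8.16% of genes in gallbladder and 7.33% in hCdH-chol had a fractional value. The TPM values deposited by the authors sum to 1000000 in each library and equal expected count over effective length, rescaled, to within 4.93e-09. TPM therefore adds no information on depth, and the counts set the precision. RSEM shares reads between near-identical genes by estimate, so values of close paralogs (HSPA1A and HSPA1B, HBA1 and HBA2, HLA genes) are uncertain. Genes are identified by the symbols in the files. Coordinates are not given, because the reference annotation used here for names and GC content is on another build.

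Expected counts summed to 41174700 in gallbladder and 43712179 in hCdH-chol and were rounded to whole numbers, and 3246 and 4480 genes were at 0. XIST, TSIX and genes annotated on the Y chromosome alone (102 in all) were left out of every table. Effective library sizes came from edgeR 4.0.16 (TMM) under R 4.3.3. The log2 ratio of hCdH-chol over gallbladder was computed after adding 0.5 to each count. A gene was measured if it had 10 counts and 1 CPM or more in at least 1 library. With 1 library per group no model with residual degrees of freedom exists, so no test was made. A gene was called higher in a library where the whole 95% exact (Clopper-Pearson) interval of the ratio, conditional on the summed count, lay beyond 2-fold. This rule compares these 2 libraries, not the conditions, and the intervals cover counting error only. Reads without molecular identifiers are not independent molecules, so the true error is larger. Where a library had 0 counts, the fold was computed against a floor of 3 counts, as a bound that leaves out the counting error of the other library. The lower limit of the exact interval lies below it, for example at 15.2 against 19.3 for SLC10A2. Folds with 1 to 3 counts in a library are given with their interval or as counts.

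The 25 gene lists, the rule for calls and the rule for named genes were fixed before the data were examined. The lists cover biliary, epithelial, hepatic and signalling genes and the cell types a gallbladder sample could hold. Named genes were the 12 per direction with the interval furthest from equality at 50 CPM or more, the 5 with the highest TPM in each library, 15 fixed biliary and hepatic genes, and up to 4 members of each list in its main direction and 2 in the other. ACTA2, TAGLN, CYP3A4, APOC3, APOA1, CYP1A1 and the genes named from the added lists were named outside this rule, after their values were seen. Some genes that the rule names are not reported here. Of the listed genes, MUC3A, MUC5AC and SLC51A are not analysed here. LGR5, CD44 and TBX3 are in both the progenitor and the Wnt lists, and GPI is in both the glycolysis and the housekeeping lists. For each list, the median log2 ratio was placed among the medians of 10000 random lists of the same size, each gene drawn from the same of 20 bins of mean log2 CPM. A list was said to stand apart below the 2.5th or above the 97.5th percentile, as a description of these libraries and not a test. In addition, 9 lists were added after the first results were seen and appear only in the closing section.

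The calling rule was tested on simulated data: Poisson counts for the 15833 measured genes at the real depths, with 200 genes changed. All 100 genes changed 4-fold and all 100 changed 8-fold were called (100.0% each), and 0 unchanged genes were called. Of 200 unchanged random lists of 20 genes, 5.0% fell outside the percentile limits. The simulated genes varied independently, so a share near this follows from the limits themselves. It does not show how lists of genes that vary together behave. This simulation holds counting noise alone and no biological variation. It held no change near the 2-fold limit, so it does not show how calls behave there. The alternatives tried were other scalings (library size, DESeq2 1.42.0 size factors, upper quartile, pan-epithelial or housekeeping median set to 0), deposited TPM in place of counts, another added count, other filters and fold limits, other random lists and, chosen after seeing the data, removal of a smooth trend on transcript length and GC content. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures from matplotlib 3.10.9.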

Results

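Poly-A RNA-seq profiles of 2 human samples were compared. The first came from gallbladder tissue. The submitters' labels give its source as tissue and its cell type as primary cholangiocytes, the epithelial cells that line the bile ducts and gallbladder. The second came from hCdH-chols, cholangiocytes differentiated in culture from human chemically induced hepatic stem cells, or hCdHs. The hCdHs had been made from primary hepatocytes with 20 ng/ml hepatocyte growth factor (HGF), 3 μM CHIR99021, an inhibitor of GSK3 that activates Wnt signalling, and 4 μM A83-01, an inhibitor of TGF-β receptors, for a week. Differentiation used 7.5 ng/ml epidermal growth factor, 7.5 μM CHIR99021 and 7.5 ng/ml HGF for 2 weeks, with 10 μM sodium taurocholate, a bile salt, on days 12 to 14. The total estimated count was 41174700 in gallbladder and 43712179 in hCdH-chol. There was 1 library per group, so no value below has a replicate check and no p-value is given. Each fold is followed by its 95% exact counting interval, which covers counting error in these 2 libraries only. The 2 libraries also differ in organ of origin and in tissue against culture, and the labels do not say whether they share a donor.

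The comparison asked how the transcriptome of the differentiated cells differed from that of gallbladder. Of 15833 measured genes, 10061 (63.5%) had an interval that did not lie wholly beyond 2-fold. Gallbladder was higher for 3921 genes and hCdH-chol for 1851, so 32.1% of the genes that differed were higher in hCdH-chol. Beyond 16-fold, 1256 genes were higher in gallbladder and 132 in hCdH-chol. At 1 CPM (counts scaled to 1000000 per library) or more, 13363 genes were detected in both libraries, 2096 in gallbladder alone and 374 in hCdH-chol alone. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.746 and Spearman's rho was 0.769. The split depended on scaling. The share of differing genes that were higher in hCdH-chol was 58.6% when the median of a pan-epithelial gene list was set to 0, a shift of 0.54 on the log2 scale for every gene, and 17.1% when a housekeeping list was set to 0, a shift of -0.40.

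**Figure D1:**
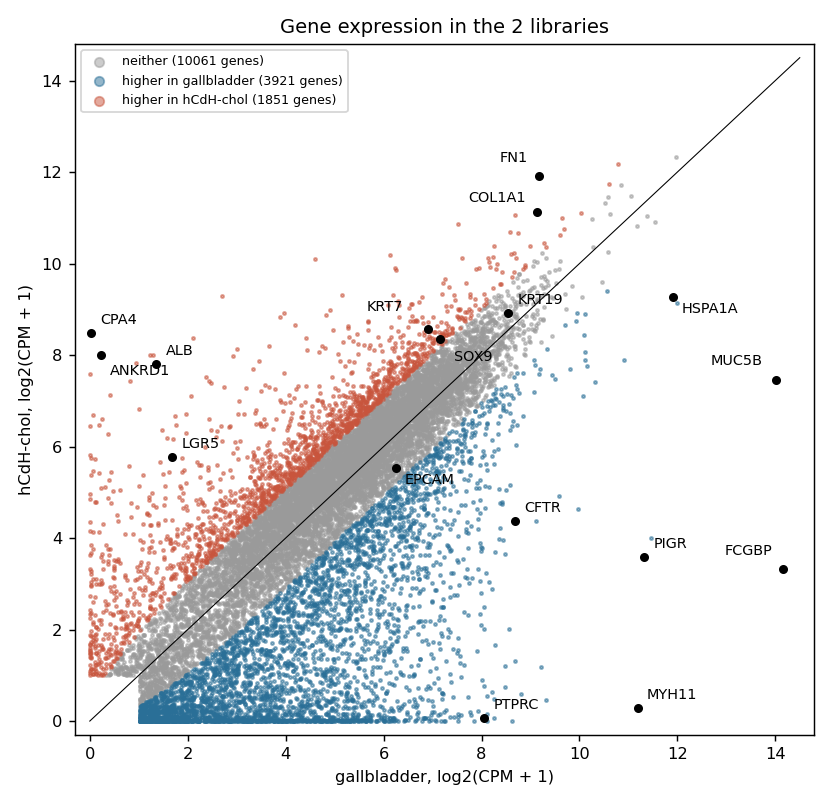
Expression of the 15833 measured genes as log2(CPM + 1) in gallbladder (x axis) and hCdH-chol (y axis), 1 library each, with the line of equal expression. Colours mark the 3921 genes higher in gallbladder, the 1851 higher in hCdH-chol and the 10061 that were neither, and black points are named genes. MYH11 and PTPRC lie at the bottom right, CPA4 at the left edge, and KRT19 and EPCAM among the grey points.

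The most abundant transcripts set the 2 samples apart. By TPM, which scales counts for transcript length and to a sum of 1000000, the gallbladder library was led by HSPA1B (5303) and HSPA1A (5217), near-identical inducible heat shock genes between which reads cannot be assigned with certainty. FCGBP (3553), a mucus-associated protein, MUC5B (2959), a gel-forming mucin, and ACTB (2824) came next. The hCdH-chol library was led by CTSD (3637 TPM), a lysosomal protease, EEF2 (3205), MIF (2938), RPL8 (2123) and ACTB (2057). FCGBP alone held 1.86% of the gallbladder counts. The 10 most abundant genes held 6.14% of the counts in gallbladder and 3.24% in hCdH-chol.

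Biliary epithelial identity genes were detected in both libraries and went both ways. KRT7, a keratin of biliary epithelium, was at 382 CPM in hCdH-chol and 119 CPM in gallbladder, 3.22-fold higher (3.12 to 3.32). SOX9, a transcription factor of the biliary lineage, was 2.32-fold higher (2.25 to 2.39), and SOX4 was 5.70-fold higher (5.51 to 5.90). KRT19 (486 and 372 CPM) and EPCAM (45.3 and 75.1 CPM, hCdH-chol first) stayed within 2-fold. With the housekeeping median set to 0, SOX9 was no longer called (log2 ratio 0.81) and EPCAM was higher in gallbladder (-1.13). ONECUT1, a biliary and hepatic transcription factor, went the other way, 31.1-fold higher in gallbladder (26.0 to 37.6). SOX17, a regulator of gallbladder and extrahepatic duct development, was 14.4-fold higher there (12.3 to 17.1), CLDN7 9.32-fold (8.64 to 10.1) and TSPAN8 5.17-fold (4.78 to 5.61). The gallbladder library also held endothelial genes (list median log2 ratio -6.72), and bulk RNA does not show which cells expressed SOX17. That library held muscle, nerve and immune cell genes too. Folds of epithelial genes in either direction, KRT7, SOX9 and SOX4 included, therefore compare whole libraries and not epithelial cells alone. Of the 18 measured identity genes, 3 were higher in hCdH-chol, 6 in gallbladder and 9 neither, which became 2 and 8 higher with the housekeeping and 4 and 4 with the pan-epithelial median set to 0. For this list the median log2 ratio (hCdH-chol over gallbladder) was -0.54, at or above only 4 of 10000 random lists matched on expression. It was 0.00 when the pan-epithelial median was set to 0, and lay at the 7.54th percentile of random lists not matched on expression.

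**Figure D2:**
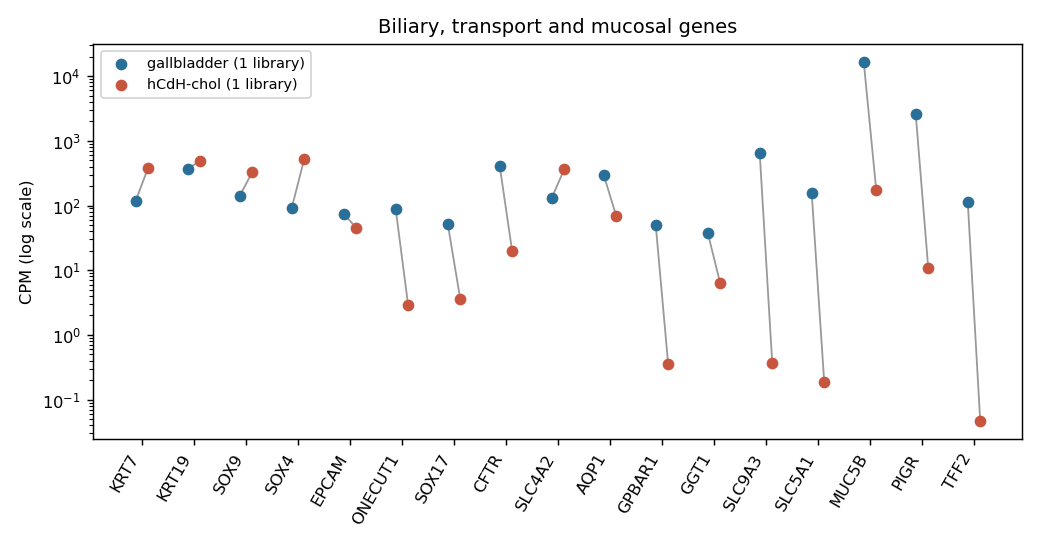
CPM on a log axis for 17 biliary, transport and mucosal genes in gallbladder and hCdH-chol, 1 library each, with a line joining both values of a gene. KRT7, SOX9 and SOX4 lie higher in hCdH-chol, KRT19 and EPCAM lie close together, and GPBAR1, SLC9A3, SLC5A1, PIGR and TFF2 are at least 143-fold apart.

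Pan-epithelial and junction genes were split. KRT18 was 2.97-fold higher (2.88 to 3.06) and CLDN1, a tight junction claudin, 5.46-fold higher (5.29 to 5.64) in hCdH-chol. GRHL2, an epithelial transcription factor, was 79.2-fold higher in gallbladder (52.6 to 125), TJP3 21.8-fold (18.7 to 25.6), the epithelial protease PRSS8 12.4-fold (11.1 to 13.8) and the epithelial splicing factor ESRP1 12.3-fold (10.7 to 14.1). Among the 24 genes, 3 were higher in hCdH-chol, 9 in gallbladder and 12 neither. The median log2 ratio of -0.54 was at or above 3 of 10000 matched random lists. With this median set to 0, 5 were higher in hCdH-chol, and among random lists not matched on expression it lay at the 4.92nd percentile.

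Genes for bile transport and modification were lower in hCdH-chol, with exceptions. CFTR, the chloride channel of biliary secretion, was at 409 CPM in gallbladder and 19.7 CPM in hCdH-chol, a 20.8-fold difference (19.4 to 22.3). The sodium-proton exchanger SLC9A3 was 1714-fold higher in gallbladder (1055 to 2999), the sodium-glucose transporter SLC5A1 823-fold (417 to 1907), the bile acid receptor GPBAR1 143-fold (86.7 to 257), VIPR1 29.8-fold (23.1 to 39.1), GGT1 6.01-fold (5.28 to 6.86) and the water channel AQP1 4.26-fold (4.09 to 4.44). SLC10A2, the apical bile acid transporter, had 57 counts in gallbladder and 0 in hCdH-chol, at least 19.3-fold higher against a floor of 3 counts. The secretin receptor SCTR had 47 and 12 counts, 3.98-fold higher in gallbladder (2.08 to 8.25). SLC4A2, the bicarbonate exchanger, was 2.77-fold higher in hCdH-chol (2.68 to 2.85) and the efflux pump ABCB1 2.59-fold (2.49 to 2.69). Of 21 measured members, 14 were higher in gallbladder, 3 in hCdH-chol, which became 1 with the housekeeping median set to 0, and 4 neither. ABCB1 lost its call under that scaling, SCTR with the pan-epithelial median set to 0 and on deposited TPM, and SLC10A2 on deposited TPM. Their median log2 ratio was -2.09, below all 10000 matched random lists. The gallbladder library held genes of several cell types, and bulk RNA does not show which cells expressed AQP1 or the other members.

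Mucins and secreted mucosal proteins were lower in hCdH-chol. MUC5B was 94.7-fold higher in gallbladder (92.6 to 96.9), MUC4 170-fold (119 to 253), LGALS4 296-fold (215 to 421) and PIGR, the receptor that carries antibodies across mucosa, 235-fold (214 to 257). The trefoil peptide TFF2 had 4807 counts in gallbladder and 2 in hCdH-chol, a ratio of 2444 (676 to 2.02e+04). Of 18 measured genes 17 were higher in gallbladder and none in hCdH-chol. Across them the median log2 ratio of -5.09 lay below all 10000 matched random lists.

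Hepatocyte genes stood above the random lists in hCdH-chol. Albumin (ALB) was at 222 CPM against 1.57 CPM in gallbladder, 142-fold higher (111 to 183), and haptoglobin (HP) was 245-fold higher (179 to 345). The fibrinogen chain FGB was 420-fold higher (250 to 769). APOA2, an apolipoprotein of high-density lipoprotein, had 8160 counts against 0, at least 2675-fold higher. CYP1A2, a drug-metabolising P450, had 1289 against 0, at least 423-fold higher. PCK1 and G6PC, enzymes of glucose production, went the other way. PCK1 was 1470-fold (574 to 5397) and G6PC 505-fold (216 to 1558) higher in gallbladder. The regulator HNF4A stayed within 2-fold, at 75.6 CPM in hCdH-chol and 49.2 CPM in gallbladder, and was higher in hCdH-chol with the pan-epithelial median set to 0 (log2 ratio 1.16). Of 24 measured hepatocyte genes, 16 were higher in hCdH-chol, 4 in gallbladder and 4 neither. The 16 and 4 became 17 and 3 with the pan-epithelial and 14 and 4 with the housekeeping median set to 0. Their median log2 ratio was 2.84, above all 10000 matched random lists. CYP3A4 had 12 counts in hCdH-chol and 19 in gallbladder, and APOC3 had 3 and 0.

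Hepatic progenitor genes were mixed. LGR5 was 24.1-fold higher in hCdH-chol (19.6 to 30.01), SALL4 7.25-fold (5.35 to 10.0), TNFRSF12A 4.51-fold (4.25 to 4.80) and NCAM1 3.03-fold (2.86 to 3.21). GPC3 was 26.9-fold (19.8 to 37.6) and ANPEP 7.98-fold (7.76 to 8.20) higher in gallbladder. Alpha-fetoprotein (AFP) was near the limit of detection, with 31 counts in hCdH-chol and 1 in gallbladder, a ratio of 30.5 (5.08 to 1242). Of 13 measured genes 5 were higher in hCdH-chol, 4 in gallbladder and 4 neither. With the pan-epithelial median set to 0, 2 were higher in gallbladder. The list median of 0.08 was within the random range and turned to -0.33 with the housekeeping median set to 0 and to -0.04 on deposited TPM.

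Wnt target genes were higher in hCdH-chol as a group. NOTUM was 100.1-fold higher (57.1 to 194), DKK1 29.5-fold (23.3 to 37.97), LGR5 24.1-fold (19.6 to 30.01) and NKD1 10.5-fold (9.85 to 11.1), all targets or feedback inhibitors of the pathway. APCDD1 was 6.13-fold higher in gallbladder (5.67 to 6.64). Of 17 measured genes 12 were higher in hCdH-chol, 1 in gallbladder and 4 neither. Their median log2 ratio was 2.96, above all 10000 matched random lists.

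Members of the Notch pathway, which acts in bile duct formation, differed in both directions. The ligand JAG1 was 4.36-fold (4.21 to 4.52) and the target HES1 2.27-fold (2.16 to 2.39) higher in hCdH-chol. HEYL was 41.8-fold (29.5 to 61.4), DLL4 19.0-fold (12.7 to 29.7), NOTCH4 17.8-fold (13.9 to 23.2) and DLL1 13.0-fold (10.8 to 15.7) higher in gallbladder. HEYL, DLL4 and NOTCH4 are also expressed by vascular cells, and the endothelial list was higher in gallbladder with a median log2 ratio of -6.72. Of 15 Notch genes 7 were higher in gallbladder, 2 in hCdH-chol and 6 neither. The 2 became 1, without HES1, with the housekeeping median set to 0, on deposited TPM and with a trend on length and GC content removed. The median was -0.99, at or above 110 of the 10000 matched random lists and at the 2.92nd percentile of lists not matched on expression.

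YAP target genes and genes of mesenchymal transition and wound repair were higher in hCdH-chol. ANKRD1 was 1532-fold higher (743 to 3811), TGFB2 17.3-fold (16.4 to 18.4), FJX1 12.6-fold (10.3 to 15.4) and AMOTL2 4.94-fold (4.68 to 5.23). F3 was 2.31-fold higher in gallbladder (2.22 to 2.42), but not called with the pan-epithelial median set to 0. Of 18 YAP targets 11 were higher in hCdH-chol, 1 in gallbladder and 6 neither, with a median log2 ratio of 1.07. The count of 11 was 5 with the housekeeping median set to 0, 6 on deposited TPM and 7 with library size or upper-quartile scaling. In the mesenchymal list, N-cadherin (CDH2) was 33.3-fold (30.6 to 36.2), the transcription factor SNAI2 11.2-fold (10.1 to 12.5) and fibronectin (FN1) 6.65-fold (6.57 to 6.75) higher in hCdH-chol. TWIST2 was 6.198-fold (3.89 to 10.4) and ZEB2 2.89-fold (2.77 to 3.02) higher in gallbladder. Of its 19 genes 10 were higher in hCdH-chol, 3 in gallbladder and 6 neither, with a median of 1.09. With the pan-epithelial median set to 0, the 10 became 12 and the 3 became 1, without ZEB2. The 10 and 3 became 7 and 4 with the housekeeping median set to 0, and 8 and 4 on deposited TPM. Both medians were at or above 9999 of the 10000 matched random lists.

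Fibroblast and stromal matrix genes were divided. COL1A1, the main chain of type I collagen, was 4.01-fold (3.96 to 4.07) and THY1 2.95-fold (2.80 to 3.10) higher in hCdH-chol. OGN was 2366-fold (1014 to 7289), FBLN1 473-fold (362 to 630) and CFD 36.6-fold (29.1 to 46.8) higher in gallbladder, and DPT had 2021 counts against 0, at least 685-fold higher. Of 19 genes 10 were higher in gallbladder, 5 in hCdH-chol and 4 neither, with a median log2 ratio of -1.14. This was below all 10000 matched random lists. The 5 became 2 with the housekeeping median set to 0 and 3 with library size scaling or on deposited TPM. With the pan-epithelial median set to 0, 7 were higher in hCdH-chol and 7 in gallbladder. The 10 higher in gallbladder also became 7 with a trend on length and GC content removed.

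Genes of other cell types of a gallbladder wall were for the most part higher in the gallbladder library, many with 0 to 9 counts in hCdH-chol. In smooth muscle, MYH11, the smooth muscle myosin, had 98276 counts against 9, KCNMB1 1238 against 0, and ACTG2 was 101-fold (80.4 to 128) and SYNPO2 42.6-fold (40.0 to 45.3) higher. In hCdH-chol 12 of the 14 smooth muscle genes were at 1 CPM or more, among them TAGLN at 161 CPM (416 CPM in gallbladder) and ACTA2 at 120 CPM (346 CPM in gallbladder). All 13 endothelial genes were higher in gallbladder, among them VWF (149 and 0.140 CPM), PLVAP (115 and 0.0467 CPM), EMCN (24.4 and 0.0467 CPM) and ROBO4 (23.4 and 0.117 CPM). All 18 lymphoid and plasma cell genes were higher. PTPRC, the pan-leukocyte marker CD45, had 11190 counts against 2, and the B cell genes MS4A1 and POU2AF1 had 11627 and 6304 against 0. The antibody-joining chain, listed under its older symbol IGJ, had 18708 against 22. All 18 measured myeloid and mast cell genes were higher, among them the mast cell tryptase TPSAB1 (5586 against 0) and the macrophage genes C1QC (2851 against 0), C1QB (2485 against 1) and CSF1R (3075 against 1). In the nerve and glia list 10 of 12 genes were higher in gallbladder, among them SCN7A (4242 against 1) and CDH19 (2661 against 4). L1CAM was 3.85-fold higher in hCdH-chol (3.70 to 4.01). In the mixed adipocyte, red cell and mesothelial list, HBA1 (2530 against 11), HBA2 (2669 against 8), HBB (453 against 0) and PLIN4 (2936 against 90) were higher in gallbladder, and CALB2 (55 against 515) and UPK3B (130 against 477) in hCdH-chol. Smooth muscle had 11 of 14 genes higher in gallbladder, none higher in hCdH-chol, and a median log2 ratio of -3.22. The medians were -6.72 for endothelial, -10.27 for lymphoid, -8.67 for myeloid and mast cell, -9.07 for nerve and glia and -4.77 for the mixed list, each below the 2.5th percentile of matched random lists. The mixed list lay at the 3.10th percentile without the filter on low counts and at the 3.31st at 5 CPM. With genes at 0 counts set to a floor of 3, the lymphoid, myeloid and nerve medians were -8.84, -8.11 and -6.76. With the pan-epithelial median set to 0, 8 smooth muscle, 12 endothelial and 16 myeloid and mast cell genes were higher in gallbladder. The endothelial count was also 12 with a trend on length and GC content removed. The smooth muscle count was 12 with the housekeeping median set to 0.

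**Figure D3:**
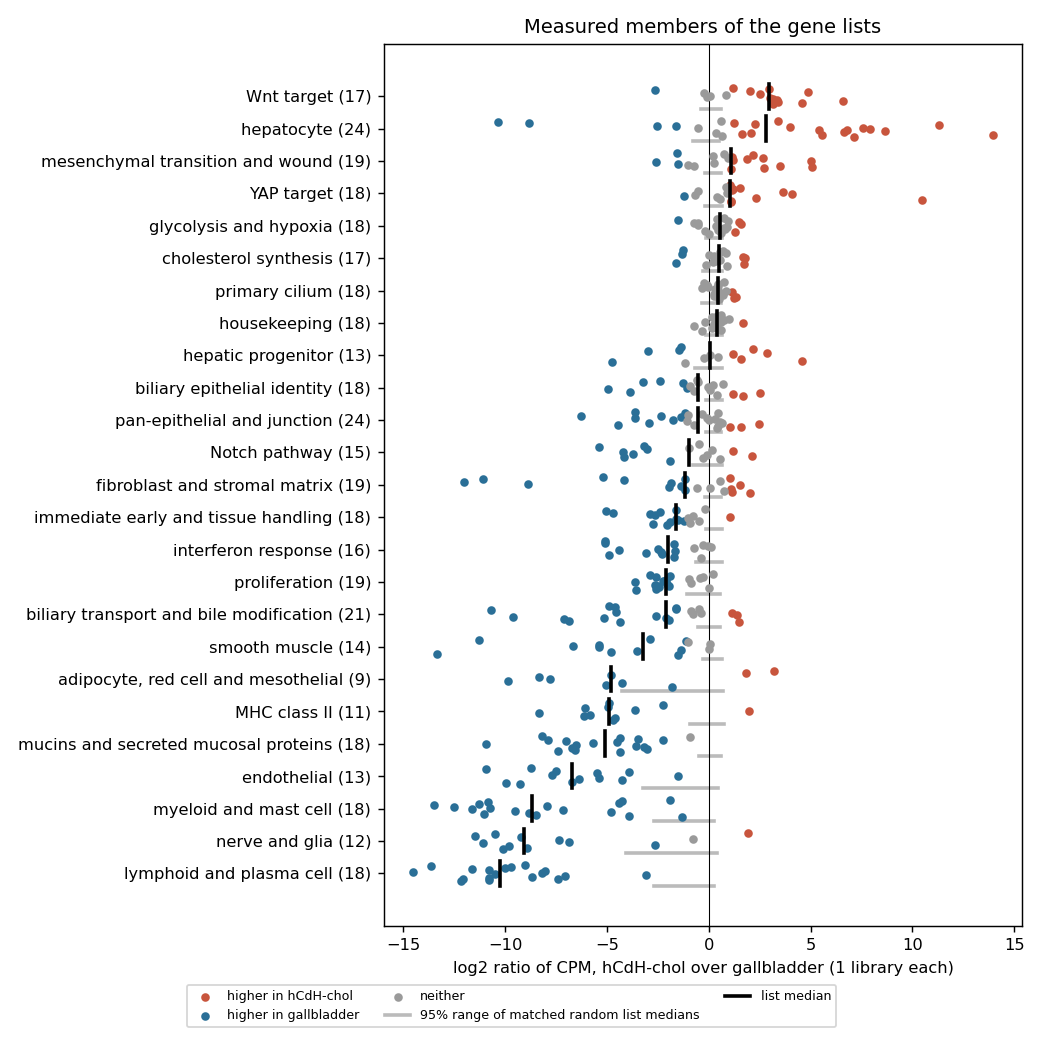
Log2 ratio of CPM (hCdH-chol over gallbladder, 1 library each) for every measured member of the 25 gene lists, whose number is given in parentheses. Points are genes coloured by their call and spread vertically for legibility, black bars are list medians and grey bars the central 95% of medians of 10000 random lists matched on expression. Medians run from -10.27 for lymphoid and plasma cell genes to 2.96 for Wnt targets.

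Antigen presentation and interferon genes were higher in gallbladder, alongside its immune cell genes. In MHC class II, HLA-DQA1 was 485-fold (86.6 to 1.92e+04), HLA-DPA1 71.3-fold (54.8 to 94.6), HLA-DMB 69.0-fold (45.8 to 109) and HLA-DPB1 57.3-fold (47.9 to 69.2) higher. HLA-DQB1 was 3.95-fold higher in hCdH-chol (3.55 to 4.39). Reads of HLA genes are hard to place on a reference, since these genes vary between people. Of 11 genes 10 were higher in gallbladder and 1 in hCdH-chol, with a median log2 ratio of -4.91, below all 10000 matched random lists. Among 16 interferon response genes 11 were higher in gallbladder and 5 neither. IFITM1 was 34.4-fold (27.6 to 43.5), ISG20 34.2-fold (29.2 to 40.5), IFI27 29.99-fold (24.3 to 37.4) and OAS2 21.2-fold (17.6 to 25.9) higher. The interferon median of -2.00 was at or above 2 of the 10000 random lists.

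Proliferation genes were lower in hCdH-chol. MKI67, a marker of dividing cells, was 11.9-fold higher in gallbladder (11.1 to 12.8), AURKB 12.6-fold (8.83 to 18.6), BUB1 6.17-fold (5.15 to 7.44) and TOP2A 5.95-fold (5.37 to 6.61). Of 19 genes 13 were higher in gallbladder and 6 neither. Their median log2 ratio of -2.09 was at or above 10 of the 10000 matched random lists. The gallbladder library in which they were higher also held the lymphoid genes above.

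Immediate early and stress genes, which respond within minutes to handling and dissociation, were higher in gallbladder. KLF2, also an endothelial gene, was 32.6-fold higher (26.7 to 40.1), NR4A1 26.2-fold (24.8 to 27.8), HSPA1B 7.25-fold (7.16 to 7.35) and FOSB 6.68-fold (6.33 to 7.05). IER3 was 2.10-fold higher in hCdH-chol (2.01 to 2.196). Of 18 genes 12 were higher in gallbladder, 1 in hCdH-chol and 5 neither. The 1 was not called with library size or upper-quartile scaling, with the housekeeping median set to 0, on deposited TPM or with a trend on length and GC content removed. The 12 higher in gallbladder became 8 with the pan-epithelial and 15 with the housekeeping median set to 0, and 14 on deposited TPM. The list median of -1.62 was below all 10000 matched random lists.

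The remaining lists stayed within the range of random lists. Among 18 primary cilium genes 3 were higher in hCdH-chol and 15 neither. The 3 were the polycystic disease genes PKHD1, 2.54-fold (2.43 to 2.65), and PKD2, 2.38-fold (2.29 to 2.46), and the kinesin KIF3A, 2.24-fold (2.13 to 2.36). The 3 became 0 with the housekeeping median set to 0, and 5 with the pan-epithelial median set to 0. KIF3A was also not called on deposited TPM. The list median was 0.45. In glycolysis and hypoxia, SLC2A3 was 2.97-fold (2.84 to 3.11), BNIP3 2.82-fold (2.54 to 3.13) and PFKP 2.47-fold (2.39 to 2.54) higher in hCdH-chol, PDK1 was 2.87-fold higher in gallbladder (2.72 to 3.04), and 14 of 18 genes were neither, with a median of 0.54. The 3 became 9 with the pan-epithelial median set to 0, where PDK1 was not called, and 1, without BNIP3 and PFKP, with the housekeeping median set to 0. In cholesterol synthesis, DHCR7 was 3.47-fold (3.27 to 3.67) and SQLE 3.37-fold (3.13 to 3.63) higher in hCdH-chol, and INSIG1 was 2.52-fold higher in gallbladder (2.37 to 2.68). Of 17 genes 3 were higher in hCdH-chol, 3 in gallbladder and 11 neither, with a median of 0.51. With the pan-epithelial median set to 0, 7 were higher in hCdH-chol and 1, not INSIG1, in gallbladder. Of 18 housekeeping genes 17 were neither and 1 was higher in hCdH-chol. Their median log2 ratio was 0.40, and 7 were higher in hCdH-chol with the pan-epithelial median set to 0.

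The genes most different among those at 50 CPM or more repeated these groups and added others. In hCdH-chol they included CPA4, a carboxypeptidase, with 15305 counts against 1, PPBP, a platelet chemokine, with 4342 against 2, SERPINB2 with 2247 against 1, BNC1 with 3773 against 6, KRT81 with 4088 against 8 and IGFBP1 with 2240 against 3. IGFL2 (2357 counts) and the glucuronosyltransferase UGT2B4 (3694 counts) had 0 counts in gallbladder, at least 773-fold and 1211-fold higher. ANKRD1, APOA2, HP and FGB completed the 12. In gallbladder FCGBP had 765355 counts against 385, a 2022-fold difference (1829 to 2240). GP2, a mucosal glycoprotein, had 9653 against 0, CEACAM7 6408 against 0, the leukocyte genes ITGB2 7687, CSF2RB 6011 and IGLL5 16660 against 0, and WDFY4 12833 against 2. IGLL5 can take reads from the immunoglobulin lambda locus it overlaps. MYH11, MS4A1, POU2AF1, PTPRC and TPSAB1 completed the 12.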

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

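With 1 library per group, no library could be left out. No paired analysis was possible because each group has 1 library and the labels give no replicate number. An alternative on FPKM was set before the data were examined and was not run, since FPKM is not used here. The 1851 genes higher in hCdH-chol became 4443 with the pan-epithelial median set to 0, 983 with the housekeeping median set to 0 and 524 with the interval required to lie beyond 4-fold, and lay between 1450 and 2347 under the other alternatives. The 3921 genes higher in gallbladder lay between 2625 and 4763. With the pan-epithelial median set to 0, the medians of the biliary identity list (0.0011) and of the pan-epithelial list (0.00, by construction) no longer lay below 0. Random lists not matched on expression left the medians of -0.5375 for biliary identity, -0.5386 for pan-epithelial and -0.9865 for Notch as they were but within the percentile limits. The mixed adipocyte, red cell and mesothelial list, at -4.7749, came within the limits without the filter (-3.0497) and at 5 CPM (-4.9095). Scalings move all genes alike and cannot change a percentile except through the filter; under the 7 alternatives that can, no other list changed its side of the limits. Adding 5 counts cannot change the calls, which do not use the added count. It did move the medians of lists with few counts, to -6.04 from -9.07 for nerve and glia and to -7.64 from -10.27 for lymphoid and plasma cell genes. Pearson's r was 0.7102 on log2(TPM + 1), 0.6869 on log2(CPM + 0.1) and 0.6345 at 5 CPM, and Spearman's rho was 0.7419 on log2(TPM + 1) and 0.7121 at 5 CPM. Genes detected in hCdH-chol alone numbered 586 at 5 CPM. The cause of these shifts was not tested. No named gene called higher in one library was called higher in the other under any of the 8 alternatives run on named genes, though some calls ended or began. Depth limits mainly genes near 0 counts, and the missing replicates limit every gene. The choice of scaling and the differences in organ and in tissue against culture are further limits, which replicates alone would not remove.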

Other observations

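All tests in this part were chosen after the main results had been seen. The genes of the added lists were chosen before their own values were seen, except TFF1 in the gastric list and LAMA5, HSPG2 and AGRN in the basement membrane list. The genes named from these lists were picked after their values were seen.

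Basement membrane genes were higher in hCdH-chol. Of 15 genes 10 were higher in hCdH-chol, none in gallbladder and 5 neither, with a median log2 ratio of 1.58, above all 10000 matched random lists. The laminin chain LAMA3 was 8.15-fold (7.84 to 8.48) and LAMB1 5.18-fold (5.04 to 5.32) higher, and the proteoglycan AGRN was 5.24-fold higher (5.15 to 5.33). Chemokine genes went both ways, with 3 of 15 higher in hCdH-chol, 7 in gallbladder and 5 neither and a median of -0.01. The neutrophil attractant CXCL5 was 12.3-fold higher in hCdH-chol (11.6 to 13.1), and CXCL12 was 15.4-fold (13.6 to 17.4) and CCL20 6.80-fold (6.26 to 7.40) higher in gallbladder. In the gastric mucosa list 5 of 7 measured genes were higher in gallbladder and 1 in hCdH-chol, with a median of -5.00. The aspartic protease CTSE (9470 against 1143 counts), the claudin CLDN18 (1064 against 0) and the gastric zymogen PGC (505 against 1) were among the 5.

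Brush border and absorptive genes were tested as a group because SLC9A3 and SLC5A1 were far higher in gallbladder. The list median was -2.7843, at or above 12 of 10000 matched random lists, with 7 of 11 measured genes higher in gallbladder and 2 in hCdH-chol. MYO7B, a brush border myosin, had 12540 counts against 24. FABP1 (1 against 290 counts) and ESPN (27 against 336) went the other way. In hCdH-chol 8 of the 11 were at 1 CPM or more, with a median of 7.85 CPM against 72.0 CPM in gallbladder.

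Genes of B cells and follicles were among those most strongly higher in gallbladder. A candidate explanation is that the sample held lymphoid follicles. A list of 16 follicle genes had a median of -9.918, below all 10000 matched random lists (-8.32 with 0 counts set to a floor of 3). Of the 16, 15 were higher in gallbladder, among them PAX5 (2919 counts against 2), CXCR5 (2157 against 1) and CCL21 (2197 against 0). In hCdH-chol 10 of the 16 had 0 to 3 counts. As all 18 lymphoid and plasma cell genes were also higher in gallbladder, this list cannot tell follicles from other lymphoid cells. Whether dividing lymphocytes account for part of the higher proliferation genes was not tested.

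The first pattern weighed is that mucin and secreted mucosal genes were far lower in hCdH-chol. A smaller share of epithelial cells in the culture would lower other epithelial genes as far, but 1 of 42 biliary identity and pan-epithelial genes (2.381%) had a ratio at or below the mucin median, which argues against it as the whole cause. With the trend on length and GC removed the mucin median was -5.4444. The trend was small, at -0.3176 and 0.3494 on the log2 scale for the 5th and 95th percentiles over genes. Its removal could therefore move the median little, and a trend of this size is argued against as the cause. Differences in organ, donor, maturity or culture may each contribute, and the design does not separate them.

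The second pattern is the stromal matrix expression of the hCdH-chol library, where COL1A1 reached 401% of its gallbladder CPM. Carry-over of gallbladder RNA is argued against, since it cannot raise a gene above its gallbladder level and lymphoid genes were at a median of 0.0572% of their gallbladder CPM (smooth muscle genes 10.98%, both lists pooled 0.3305%), and IGLL5, at 16660 counts in gallbladder, had none, which allows up to 0.018%. Stromal cells in the culture could account for it. A list of 12 genes taken as fibroblast-restricted had a median of 15.9882 CPM in hCdH-chol (23.96 in gallbladder). Of these, FAP (2123 counts against 149) and OSR1 (1168 against 225) were higher in hCdH-chol and 6 were higher in gallbladder. Whether these genes were restricted to fibroblasts here was not tested. A hepatic stellate list was alike, with 2 of 9 measured genes higher in hCdH-chol and 5 in gallbladder (median -1.64). In hCdH-chol 8 of these 9 were at 1 CPM or more, with a median of 13.0 CPM (27.3 in gallbladder). Relative to gallbladder both lists lay low among matched random lists, at the 2.12th percentile for the list of 12 and the 1.045th for the stellate list. Expression by the hepatocyte-derived cells themselves cannot be told apart from stromal cells in the culture. Of the 12 genes taken as fibroblast-restricted, 11 were at 1 CPM or more in a pooled culture that does not show which cells held them.

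The third pattern is that hepatocyte genes were uneven in hCdH-chol, with APOA2 at 8160 counts, APOA1 at 65 and APOC3 at 3. Unchanged hepatocytes carried over would bring APOA1 and APOC3 with APOA2, yet APOA1 was at 0.7965% of the CPM of APOA2. That ratio restates the pattern and no hepatocyte library is analysed here, so it is no separate test of carry-over. Loss of short transcripts is argued against, since APOA2 is 0.5273 times as long as APOA1 (473 and 897 bases). Partial retention of a hepatocyte programme through reprogramming may account for it and was not tested, as the hepatocytes and hCdHs before differentiation are not analysed here.

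Other groups gave weaker or negative answers. CYP1A1 (4124 counts against 184) and CYP1A2 were higher in hCdH-chol, and 10 other targets of the aryl hydrocarbon receptor were tested as a group. Their median of 0.569 lay within the random range, with 4 higher in hCdH-chol, 1 in gallbladder and 5 neither, which leaves a shared change open. KRT81, BNC1 and SERPINB2 were higher in hCdH-chol, but a basal and squamous list was not, with a median of -2.8033, none of 9 measured genes higher in hCdH-chol and 6 in gallbladder. That median was within the random range, at the 9.77th percentile. Expression of the list was low, with a median of 0.678 CPM in hCdH-chol and 6.23 CPM in gallbladder.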
